A study of Saccharomyces cerevisiae S288C with 9 samples.

How the data were processed

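The series holds RNA sequencing of 9 yeast libraries, 3 each of WT, Set1 S228A and Set1 S228E. The authors deposited 1 table of raw counts per annotated gene for all 9 libraries, with whole numbers and no normalization. Per the file headers, these counts were made with featureCounts 2.0.1 from paired-end alignments, over exons grouped by gene identifier, with the Ensembl gene annotation of the sacCer3 genome. The command in the file headers sets no strand option and no option for multiply placed reads, so the counts take reads of both strands and leave out reads placed at several sites. The submitters' processing notes name Bowtie 0.12.2 and sacCer3 without saying which data they apply to, so the aligner of these RNA reads is not given in the sources used here. Per the labels' protocols the libraries were made with a KAPA kit; the extraction text in the labels describes chromatin immunoprecipitation, while the series' design text describes phenol-chloroform extraction of total RNA. How ribosomal RNA was removed and whether the kit keeps strand are not given in the sources used here. The table's columns are named by a letter and a number, and were matched to the strains and replicates of the labels by the initial of the genotype and the replicate number.

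Counting without strand means that reads of a gene and of an unannotated transcript on its other strand fall into the same row. Leaving out multiply placed reads lowers rows of repeated genes (transposons, tRNA genes, ASP3, the histone and ribosomal protein pairs) and makes their split uncertain. Row identifiers were matched to gene symbols through the RefSeq annotation of the R64 assembly: 6047 of 7127 rows had a RefSeq locus tag, and 6038 of those had identical start and end. Coordinates in the text are those of the deposited table. No row was a total or an unassigned class. The 55 mitochondrial rows held 0 to 12 counts per library and were not tested.

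Totals per library ranged from 14455017 to 19658103 counts, with TMM factors from 0.972 to 1.03. The common biological coefficient of variation was 9.61%. Pairs of replicates differed by more than counting noise (chi-square per gene from 6.34 to 58.2), so no library was treated as a duplicate. The first principal component of log CPM held 74.2% of the variance and separated the S228A libraries from the other 6. The design text calls the replicates biological. Floors and counting intervals cover counting error only, since reads copied by PCR are not independent molecules.

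Genes were filtered with filterByExpr, scaled with TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) in 1 fit over all 9 libraries with a term per strain. A call needed a Benjamini-Hochberg adjusted p under 0.05 and a fold change over 1.5 in either direction, the thresholds of the series' design text. The comparisons made were 3: S228A against WT, S228E against WT, and S228E against S228A. Standard errors are the absolute log2 fold change divided by the square root of the F statistic, and 95% intervals use the normal distribution. These intervals are somewhat narrower than the F test implies. For SDC1 in S228A against WT the interval of -0.454 to -0.0225 left out 0 at an unadjusted edgeR p of 0.0505. A fold against a group with 0 counts is given against a floor of 3 counts over the group.

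Gene lists (47, covering COMPASS and other chromatin complexes, histones, growth, stress, metabolism, mating type, pheromone response and cell cycle) were fixed before the data were examined, as were the tests of genes and lists, the thresholds, the alternatives and the rule for named genes. Lists with 3 or more tested members (45) were tested with camera of limma 3.58.1 on log CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each test was repeated with a correlation estimated from the data and with fry. Fry's p tests whether the genes of a set move on balance in 1 direction and does not compare the set with other genes. Counts of called members over all genes tested equalled those adjusted over the list alone in the report except where both are given. The lists on mating type, pheromone response and cell cycle share some genes.

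Named genes were, in S228A or S228E against WT, up to 10 per direction with the largest fold change among called genes whose 3 values in the mutant all lay on 1 side of the 3 WT values, at a mean of at least 5 CPM over the 9 libraries. In S228E against S228A up to 5 per direction were taken. Where fewer than 5 genes were called in a direction, the 5 with the smallest p at 5 CPM or more were taken instead. For each list described, up to 4 members with the smallest p were named, and SET1 and the other COMPASS subunits always. Transposon, tRNA, snoRNA and rRNA rows were given as counts of a class, except rows said in the text to be chosen after their values were seen.

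The test was checked on simulated counts drawn from the WT means, dispersions and library sizes over 6089 genes, 200 of them changed per mutant. For S228A against WT 80.3% of genes changed 1.5-fold, 93.9% of genes changed 2-fold and 96.9% of genes changed 4-fold had an adjusted p under 0.05 in edgeR; for S228E against WT these were 83.6%, 94.0% and 100%, and for S228E against S228A 87.7%, 94.5% and 100%. With the fold threshold of a call added, 51.5%, 47.8% and 48.5% of genes changed 1.5-fold remained in the 3 comparisons, and the shares at 2-fold and 4-fold stayed the same. Of 5892, 5890 and 5699 unchanged genes 12, 20 and 21 had an adjusted p under 0.05, and 5, 7 and 7 also passed the fold threshold. A list shifted by log2 0.6 in simulated S228A libraries was called and 0 of the other lists were. Genes were drawn independently, so this does not check false list calls where the genes of a list vary together. The estimated inter-gene correlation of cytosolic ribosomal proteins, for example, was 0.665 in S228A against WT.

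Alternatives were DESeq2 size factors and upper-quartile scaling in the edgeR fit, no filter and a stricter filter of 10 CPM in 3 libraries, DESeq2 1.42.0 and limma-voom, only the 6 libraries of a comparison, the replicate number as a block, other fold thresholds and glmTreat, robust shrinkage, protein-coding nuclear genes alone, subtelomeric windows of 20 and 50 kb, and leaving out each library in turn. Fold changes of both mutants were set beside 50 simulations of unchanged groups. In these all 9 libraries, WT included, were drawn from the WT means, each gene independently. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.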

Results

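RNA was sequenced from budding yeast (Saccharomyces cerevisiae, strain S288C) grown in rich glucose medium (YPD) to mid-log phase. The strains carried either wild-type (WT) SET1 or 1 of 2 substitutions of a serine of Set1, to alanine (S228A) or to glutamate (S228E). Set1 is the catalytic subunit of COMPASS, the complex that methylates histone H3 at lysine 4; glutamate is often used to imitate a phosphorylated serine, and alanine cannot be phosphorylated. Each strain was represented by 3 libraries, described by the submitters as biological replicates. The total of the gene counts per library ranged from 14455017 to 19658103, and 6133 of the 7127 annotated rows had enough counts to be tested. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test and a fold change over 1.5, and levels are TMM-normalized counts scaled to library size (counts per 1e6, CPM), given as mean ± SD of 3 libraries.

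The SET1 transcript (YHR119W, chromosome VIII, 346043 to 349285, sacCer3) was present at a like level in the 3 strains, with 199.8 ± 6.25 CPM in WT, 203.1 ± 18.1 CPM in S228A and 218.9 ± 15.1 CPM in S228E (n = 3 each). Its log2 fold change was 0.02 ± 0.08 (SE) in S228A (edgeR adjusted p = 0.857) and 0.13 ± 0.08 in S228E (edgeR adjusted p = 0.855). A codon change need not move the transcript, so this level does not check the strain labels. None of the 8 COMPASS subunit genes was called in any of the 3 comparisons. The member with the smallest p in S228A was SPP1 at log2 -0.31 ± 0.08 (edgeR adjusted p = 0.0115), followed by SWD3 at -0.38 ± 0.14 (edgeR adjusted p = 0.0482), both short of the 1.5-fold threshold.

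The comparison of S228A with WT asked how loss of the serine altered the transcriptome. The S228A libraries held the transcripts of the yeast mating response at high level. FIG1 (YBR040W, chromosome II, 316968 to 317864), a membrane protein made during mating, was at 1.32 ± 1.10 CPM in WT and 1275 ± 83.3 CPM in S228A (n = 3 each), a log2 fold change of 9.93 ± 0.28 (SE; edgeR adjusted p = 6.07e-11). AGA1, the anchor subunit of the agglutinin that joins mating cells, was 45.1-fold higher, from 96.8 ± 33.2 to 4362 ± 242 CPM, and FUS1, which acts in cell fusion, was 14.2-fold higher, from 24.6 ± 6.04 to 348.4 ± 144.3 CPM. Transcripts of dividing cells were low in the same libraries: the histone H2B gene HTB2 fell from 623.9 ± 69.5 to 39.1 ± 6.50 CPM, and the mitotic cyclin gene CLB1 from 74.3 ± 12.9 to 5.01 ± 1.41 CPM. In all, 747 genes were called, 268 higher and 479 lower in S228A, of which 198 and 458 were protein-coding.

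The 10 largest increases among the genes that met the naming rule were FIG1, PRM6, FIG2, PRM1, FUS2, AGA1, ASG7, PRM3, PRM2 and FUS1, with log2 fold changes from 9.93 down to 3.83. For all of them the 3 S228A values lay above the 3 WT values, as the naming rule required. PRM6 was at 0.292 ± 0.153 CPM in WT and at 133.9 ± 38.8 CPM in S228A. The 10 largest decreases were PCL1, TOS6, FDO1, HTB2, FIT1, CLB1, TOS4, HTA2, HHF2 and AIM20, from -5.14 to -3.46. PCL1, a G1 cyclin of the Pho85 kinase, was at 11.1 ± 4.86 CPM in WT and at 0.316 ± 0.206 CPM in S228A, a log2 fold change of -5.14 ± 0.57 (edgeR adjusted p = 1.87e-05). FIT1, a cell wall protein that retains iron carriers, fell by 3.95 on the log2 scale (SE 0.36; edgeR adjusted p = 2.88e-06), and its WT values ranged widely, at 138.6 ± 55.6 CPM.

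**Figure D1:**
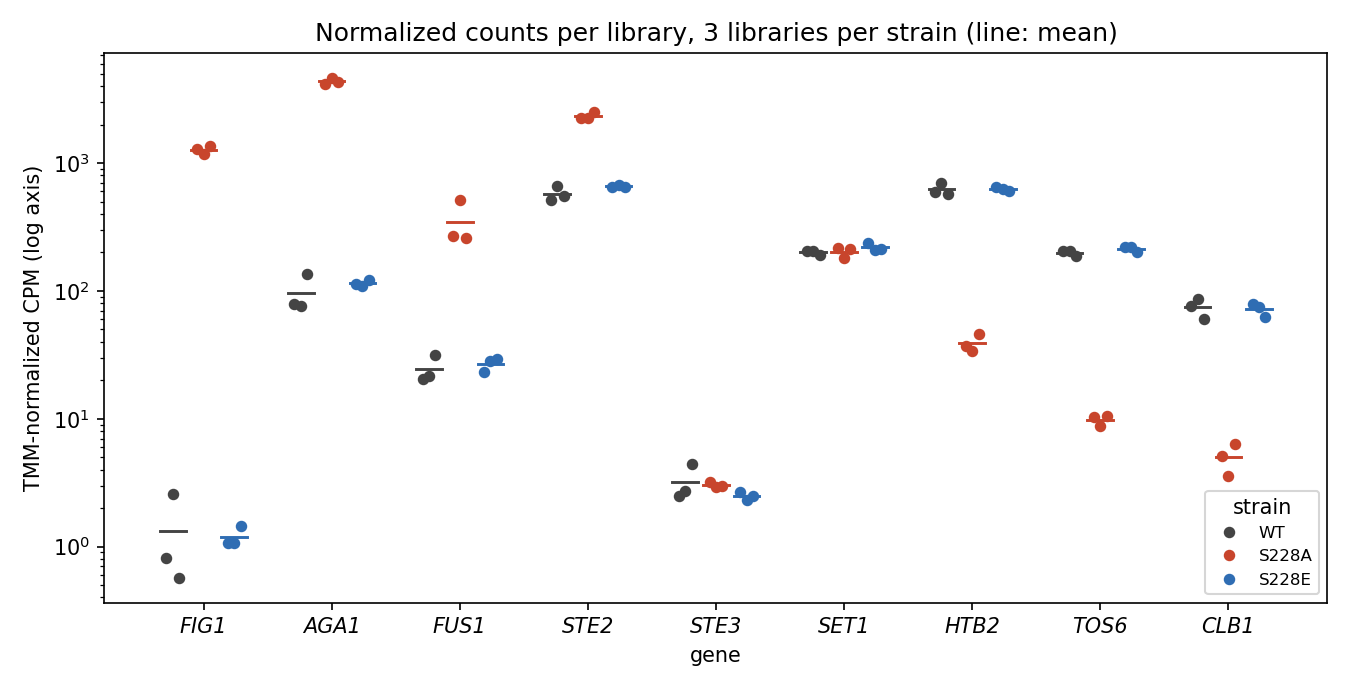
Points are TMM-normalized CPM of single libraries (log axis) and lines are means of 3 libraries per strain, for 9 genes of the text. FIG1, AGA1, FUS1 and STE2 stood higher and HTB2, TOS6 and CLB1 lower in the 3 S228A libraries (FIG1 at 1275 CPM against 1.32 CPM in WT), while STE3 stayed near 3 CPM and SET1 near 200 CPM in each strain.

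All 20 tested genes of the pheromone response list rose in S228A, as many when adjusted over the list alone, with log2 fold changes from 0.88 to 9.93 and a median of 3.31. The list stood apart from other genes (camera adjusted p = 7.15e-22 with a preset correlation; adjusted p = 0.0861 with an estimated correlation). Beside FIG1, the members with the smallest p were PRM3 at log2 4.44 ± 0.13, PRM2 at 4.11 ± 0.13 and SST2, a negative regulator of the pheromone pathway, at 2.75 ± 0.09 (edgeR adjusted p at most 1.48e-10). All 7 a-specific genes, which are made by cells of mating type a, rose (camera adjusted p = 4.74e-10; adjusted p = 0.0908 with an estimated correlation), among them ASG7 at log2 5.0 ± 0.12, AGA2 at 3.70 ± 0.15, BAR1 at 2.68 ± 0.11 and the pheromone receptor gene STE2 at 2.02 ± 0.10. Of 11 haploid-specific genes 5 rose and none fell (camera adjusted p = 4.20e-05; adjusted p = 0.0629 with an estimated correlation), including FUS3 at log2 1.76 ± 0.10 and FAR1 at 1.77 ± 0.12, both of them also members of the pheromone response list.

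Markers of the opposite mating type did not move together. Of 5 alpha-specific genes 2 rose, or 3 when adjusted over the list alone (camera adjusted p = 0.0324; adjusted p = 0.236 with an estimated correlation). SAG1 was at log2 1.72 ± 0.13 (edgeR adjusted p = 5.30e-07) and MF(ALPHA)2 at 0.98 ± 0.18 (edgeR adjusted p = 0.00134). STE3, the receptor gene of alpha cells, was at 3.22 ± 1.08 CPM in WT and 3.04 ± 0.138 CPM in S228A, a log2 fold change of -0.08 ± 0.24 (edgeR adjusted p = 0.828). MF(ALPHA)1, which encodes alpha-factor, was at 0.426 ± 0.239 CPM in WT and 0.856 ± 0.0725 CPM in S228A (edgeR adjusted p = 0.0876; called without WT replicate 2). In WT the a-cell gene STE2 was at 577.6 ± 77.1 CPM.

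Histone and cell cycle genes fell. All 11 genes of the core histone and variant list were lower in S228A, as many when adjusted over the list alone (median log2 -2.33; camera adjusted p = 1.99e-14; adjusted p = 0.0510 with an estimated correlation), with HHF2 at -3.62 ± 0.08, HTA2 at -3.62 ± 0.10, the linker histone gene HHO1 at -2.57 ± 0.08 and HTB2 at -4.00 ± 0.12. Reads that fit both genes of a histone pair were not counted, so the split within a pair is uncertain. Of 26 G1/S genes 22 fell, 1 rose and 3 were not called (camera adjusted p = 3.40e-14; adjusted p = 0.0861 with an estimated correlation), among them TOS4 at log2 -3.66 ± 0.13, the G1 cyclin gene CLN1 at -2.69 ± 0.10, GIN4 at -2.82 ± 0.11 and the ribonucleotide reductase gene RNR1 at -3.06 ± 0.17. The member that rose was the cyclin gene PCL2, at log2 3.06 ± 0.28, named after its value was seen. Of 15 G2/M genes 13 fell and none rose (camera adjusted p = 6.77e-15; adjusted p = 0.0510 with an estimated correlation), with the transcription factor gene SWI5 at -3.23 ± 0.13, CHS2 at -2.68 ± 0.11, HOF1 at -3.06 ± 0.13 and HST3 at -2.09 ± 0.10.

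Smaller shifts appeared in 9 further lists at the preset correlation. Of all 16 lists called in this comparison, those described above included, 0 held with an estimated correlation. Fry, which does not compare a list with other genes, called 19 of 45. The fry adjusted p was 1.63e-06 for pheromone response, 7.12e-08 for histone, 3.78e-06 for G1/S and 4.05e-07 for G2/M genes. Directions were those of camera. For cytosolic ribosomal proteins the fry adjusted p was 0.128. Of 51 general stress genes 14 fell and none rose, with HSP12 at log2 -2.97 ± 0.26 and YGP1 at -1.59 ± 0.20 (camera adjusted p = 0.00486; adjusted p = 0.775 with an estimated correlation). Of 17 phosphate regulon genes 6 fell and none rose, with SPL2 at -1.20 ± 0.10 and the phosphate transporter gene PHO84 at -0.84 ± 0.10 (camera adjusted p = 0.00855; adjusted p = 0.701 with an estimated correlation). Of 25 genes of nitrogen catabolite repression 5 fell and none rose, with CAR2 at -1.26 ± 0.14 and MEP2 at -1.13 ± 0.15 (camera adjusted p = 0.00268; adjusted p = 0.337 with an estimated correlation). Of 35 nuclear genes of the respiratory chain 2 fell (camera adjusted p = 0.0186; adjusted p = 0.775 with an estimated correlation). Of 22 Hsf1 chaperone genes 3 rose and 1 fell, CPR6 at 0.79 ± 0.10 and HSP26 at -2.14 ± 0.37 (camera adjusted p = 0.00986; adjusted p = 0.701 with an estimated correlation). Among the flocculins 1 of 6 rose, FIG2 at 6.01 ± 0.21, a pheromone-induced gene that the pheromone response list also holds (camera adjusted p = 0.0136; adjusted p = 0.236 with an estimated correlation).

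Among the growth lists, 0 of 135 cytosolic ribosomal protein genes and 0 of 20 RNA polymerase I and III subunit genes were called, and 1 of 94 ribosome biogenesis genes rose, ESF1 at log2 0.60 ± 0.08. Their medians were 0.21, 0.23 and 0.14, with camera adjusted p of 1.80e-07, 0.00486 and 0.00173, and adjusted p = 0.775, 0.775 and 0.801 with an estimated correlation. The ESF1 call was lost in 3 of 16 alternative settings, and RPC11, RPS21B and RPL15B, not called here, were called in 4, 3 and 1 of 16. The other 29 of the 45 tested lists were not called by camera in this comparison, the COMPASS list among them (camera adjusted p = 0.668).

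Many transposon and tRNA rows rose in S228A. Over all 6133 tested rows 268 were called higher and 479 lower. Of 261 tested rows unmatched or annotated as noncoding 14 were called higher and 20 lower. Of 74 snoRNA and other small RNA rows 1 was lower, and of 5 rRNA rows 1 was higher. Of 55 tested transposon rows 43 were called higher and none lower, and their share of all gene counts was 0.159% to 0.183% in the WT libraries, 0.575% to 0.650% in S228A and 0.182% to 0.210% in S228E. The Ty3 row YIL082W-A went from 62.3 ± 6.51 to 1547 ± 143 CPM, and YCL075W from 0 counts in the 3 WT libraries to 23.9 ± 7.33 CPM, at least 431-fold higher against a floor of 3 counts over the WT group. Of 20 tested tRNA rows, among 275 in the annotation, 12 rose and none fell. Rows with few reads in WT and S228E passed the count filter only through the S228A libraries, which favours rows that rose. tR(UCU)G3 (chromosome VII, 736340 to 736411) was at 0.257 ± 0.200 CPM in WT and 42.8 ± 5.10 CPM in S228A, and tH(GUG)E2 (chromosome V, 434541 to 434612) at 0.134 ± 0.138 and 39.6 ± 6.56 CPM. These 4 rows were chosen after their values were seen. Counting without strand and without multiply placed reads leaves open which copy or neighbouring transcript such reads came from.

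**Figure D2:**
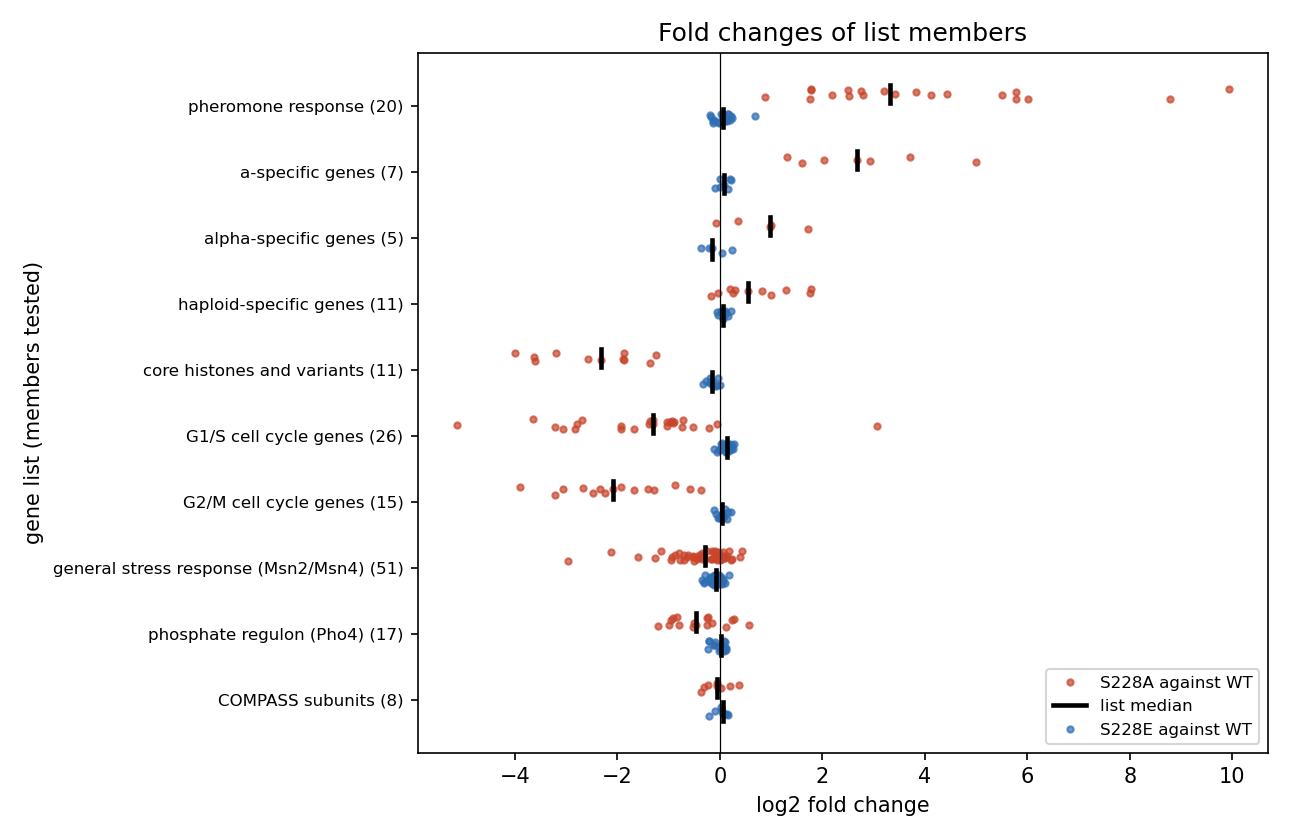
Each point is the log2 fold change of 1 member of a gene list against WT, in S228A (red) or S228E (blue), and black bars are list medians; the number of members tested stands in brackets. In S228A the 20 pheromone response genes had a median of 3.31 and the 11 histone genes a median of -2.33, while the S228E points lay close to 0.

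The comparison of S228E with WT asked the same of the glutamate substitution, and it called few genes. Of 6133 genes 3 were called, 2 higher and 1 lower in S228E. QRI5 (YLR204W, chromosome XII, 552270 to 552605), a mitochondrial protein gene, fell from 38.5 ± 2.01 to 24.7 ± 1.14 CPM (n = 3 each), a log2 fold change of -0.64 ± 0.09 (edgeR adjusted p = 0.0190). The transposon row YAR009C rose from 44.0 ± 0.770 to 71.8 ± 2.81 CPM (log2 0.71 ± 0.07; edgeR adjusted p = 0.00313). YLR161W, 1 of several near-identical open reading frames beside the ASP3 genes and so uncertain, was at 0.330 ± 0.137 CPM in WT and 2.28 ± 0.621 CPM in S228E (edgeR adjusted p = 0.0259). Among the alternative settings of scaling, filter, tool, block and samples, the call of YAR009C held in 15 of 15, that of QRI5 in 9 of 16 and that of YLR161W in 7 of 15, with adjusted p up to 0.0383, 0.164 and 0.164. At an unadjusted p under 0.05 edgeR gave 345 genes, 5.63% of those tested; DESeq2 called 5 genes and limma-voom 2.

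The mating and cell cycle genes were near their WT levels in S228E. FIG1 was at 1.20 ± 0.225 CPM (log2 -0.14 ± 0.43, 95% interval -0.98 to 0.70; edgeR adjusted p = 0.982), AGA1 at 114.5 ± 6.16 CPM, HTB2 at 626.7 ± 19.9 CPM and CLB1 at 72.1 ± 9.07 CPM. With transposon rows such as YAR009C left out, the 5 smallest p in the upward direction at 5 CPM or more belonged to ASP3-4, ASP3-1, OAR1, HDA2 and POL2, and in the downward direction to QRI5, RGI1, CBP4, SPO1 and MRPS18. RGI1 was at log2 -0.70 ± 0.15 (edgeR adjusted p = 0.474) and ASP3-4, from a family of near-identical copies, at 1.68 ± 0.31 (edgeR adjusted p = 0.189). Alternative settings called RGI1 in 1 of 16 and ASP3-4 in 2 of 15, DESeq2 in both cases among them. ASP3-1 was at 16.4 ± 27.3 CPM, a mean set by S228E replicate 2.

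No member of any tested list was called in S228E. Camera with the preset correlation nevertheless placed 9 of 45 lists apart, 2 upward and 7 downward, with medians from -0.20 to 0.14. Leaving out 1 library gave 5 to 17 lists. The ribosome biogenesis list had the smallest p (median log2 0.10; camera adjusted p = 6.82e-06; adjusted p = 0.813 with an estimated correlation). The core histone list had a median of -0.15 (camera adjusted p = 0.00151; adjusted p = 0.720 with an estimated correlation) and the 26 G1/S genes a median of 0.14 (camera adjusted p = 0.00341; adjusted p = 0.813 with an estimated correlation). Among 356 subtelomeric genes, within 30 kb of a chromosome end, the median was -0.07 (camera adjusted p = 0.00265; adjusted p = 0.611 with an estimated correlation, and 0.0689 with a window of 50 kb). For the respiratory chain, the cytosolic ribosomal proteins, glucose-repressed carbon use, general stress and the hexose transporters the medians were -0.07, -0.04, -0.18, -0.07 and -0.20 (camera adjusted p = 0.00526, 0.0112, 0.0112, 0.0223 and 0.0286; adjusted p = 0.813, 0.869, 0.813, 0.813 and 0.813 with an estimated correlation). The direction of the cytosolic ribosomal protein, general stress and glucose-repressed carbon lists turned when 1 library was left out. None of the 9 held with an estimated correlation, and fry, which tests whether the genes of a set move on balance in 1 direction, called 0 of 45.

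S228E and S228A were then compared directly, which is the test of whether the 2 strains differed from the shared WT in different ways. FIG1 was lower in S228E by a log2 fold change of -10.07 ± 0.28 (edgeR adjusted p = 6.05e-11), followed by PRM6, FIG2, PRM1 and FUS2. PCL1 was higher at 5.42 ± 0.57 (edgeR adjusted p = 1.03e-05), followed by TOS6, FDO1, HTB2 and CLB1. In all 680 genes were called, 413 higher and 267 lower in S228E. Of the 268 genes called higher in S228A against WT, 85.1% were called lower in S228E than in S228A, and of the 479 called lower 368 were called higher. Independent lists of these sizes would share 11.7 and 32.3 genes. Unchanged simulated groups shared at most 1 and 0 but had 3 or fewer genes called in S228A against WT. They therefore do not measure what the shared S228A libraries add to these overlaps, and part of the excess may come from those libraries. Over all genes the fold changes of S228A against WT and of S228E against S228A had a covariance of -0.468. The simulated mean was -0.0135 and the lowest simulated value -0.0161. An effect in S228A alone, which the unchanged groups lack, also makes this covariance negative, so the gap does not show a change in S228E.

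The lists called between S228A and WT had medians of the opposite sign here. Sharing the S228A libraries favours this without any change: simulated unchanged groups gave a mean Pearson correlation of -0.500 between the 2 comparisons. The Rpd3 and Set3, subtelomeric and proteasome lists were called here but not between S228A and WT. All 20 pheromone response genes and all 7 a-specific genes were lower in S228E than in S228A (camera adjusted p = 8.07e-23 and 2.24e-10; adjusted p = 0.0723 and 0.0860 with an estimated correlation). All 11 histone genes were higher (camera adjusted p = 2.02e-15; adjusted p = 0.0390 with an estimated correlation), as were 14 of 15 G2/M genes (camera adjusted p = 1.01e-16; adjusted p = 0.0390 with an estimated correlation). Of the 26 G1/S genes 22 were higher and 1 lower (camera adjusted p = 1.01e-16; adjusted p = 0.0720 with an estimated correlation). In the phosphate regulon 8 of 17 genes were higher and none lower, or 8 and 1 when adjusted over the list alone, with SPL2 at log2 0.99 ± 0.10 and PHO84 at 0.93 ± 0.10 (camera adjusted p = 0.00361; adjusted p = 0.586 with an estimated correlation). Among the Rpd3 and Set3 deacetylase genes 1 of 20 was lower, HOS2 at -0.92 ± 0.11 (camera adjusted p = 0.0431 upward; adjusted p = 0.295 with an estimated correlation). Of 11 haploid-specific genes 5, of 5 alpha-specific genes 2 and of 6 flocculins 1 were lower (camera adjusted p = 7.77e-05, 0.0156 and 0.0431; adjusted p = 0.0720, 0.138 and 0.318 with an estimated correlation). Of 25 genes of nitrogen catabolite repression 4 and of 51 general stress genes 10 were higher, HSP12 at 2.98 ± 0.26 among them (camera adjusted p = 0.0188 and 0.0431; adjusted p = 0.443 and 0.815 with an estimated correlation). Of 356 subtelomeric genes 15 were higher and 37 lower, and of 22 Hsf1 chaperone genes 1 was higher and 3 were lower (camera adjusted p = 0.00353 and 0.0408, both downward; adjusted p = 0.128 and 0.723 with an estimated correlation). With a window of 50 kb the subtelomeric call was lost (camera adjusted p = 0.0793). No cytosolic ribosomal protein, RNA polymerase I and III or proteasome gene was called (camera adjusted p = 6.89e-12, 0.0431 and 0.0431, all downward; adjusted p = 0.723, 0.809 and 0.799 with an estimated correlation). Of 45 lists 17 were called with the preset correlation and only the histone and G2/M lists with an estimated one. Leaving out 1 library gave 11 to 20, and fry called 20 of 45.

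**Figure D3:**
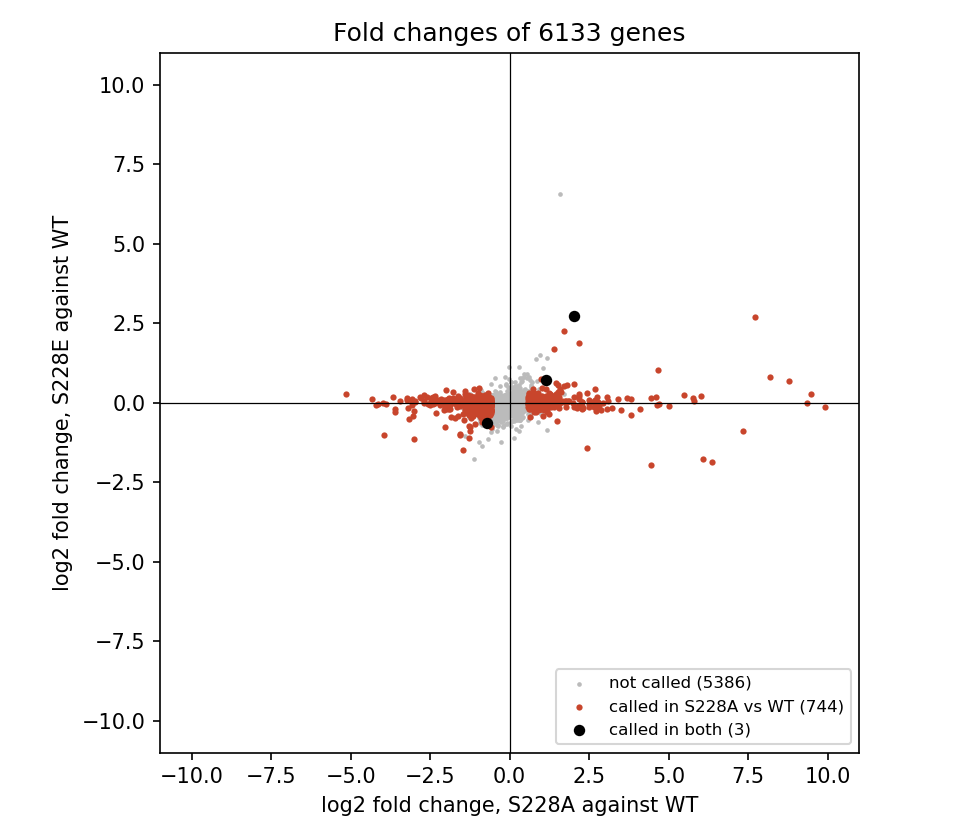
Each point is 1 of the 6133 tested genes, with its log2 fold change in S228A against WT on the x axis and in S228E against WT on the y axis, on the same scale. The 747 genes called in S228A spread along the x axis, and the 3 genes called in both comparisons (black) are YLR161W, YAR009C and QRI5.

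Across the 6133 genes, which are not independent replicates, the fold changes of S228A and S228E against WT had a Pearson correlation of 0.175 and a Spearman correlation of 0.299. Unchanged groups, with all libraries drawn from the WT means, gave a mean Pearson correlation of 0.495 and Spearman correlation of 0.467 over 50 simulations. In the simulations, as in the data, both comparisons used the same 3 WT libraries. The covariance was 0.0255, against a simulated mean of 0.0133 and a highest simulated value of 0.0158, a difference of 0.0122. Genes were drawn independently, so the simulated range leaves out variation that genes of the real WT libraries share. The difference therefore does not show an effect beyond the shared WT libraries. QRI5, YAR009C and YLR161W, the 3 genes called in S228E, were also called in S228A in the same direction, with the S228E calls of QRI5 and YLR161W lost in several settings (QRI5 at log2 -0.70 ± 0.09, YAR009C at 1.15 ± 0.07 and YLR161W at 2.03 ± 0.42). Of these, 2 were higher and 1 lower in both. Independent lists would share an expected number of 0.0874 genes among those higher and 0.0781 genes among those lower. The simulations, with 3 or fewer genes called in either mutant, shared 0.0400 and 0 genes on average. The 3 WT libraries are too few to be divided between the comparisons, so part of the excess may come from the shared controls.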

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

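The tests of opposite-mating-type RNA, of a swap of single libraries and of a culture condition were chosen only after their results were seen; the test of power was written down after the called genes were known but before it was run, with the fold threshold added to it after its result was seen, and the splits were planned before the data were examined. These results stand out because S228E and S228A libraries differed when tested directly: 680 genes were called by edgeR and 17 gene lists by camera, of which 2 held with an estimated correlation, and leaving out 1 library gave 11 to 20. The named genes with the largest differences, as log2 fold changes of S228E against S228A, were FIG1 at -10.07, PRM6 at -8.10, FIG2 at -5.80, PRM1 at -5.72 and FUS2 at -5.62, and PCL1 at 5.42, TOS6 at 4.44, FDO1 at 4.14, HTB2 at 4.0 and CLB1 at 3.85. Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05: with only the 6 libraries in the fit, S228A against WT called 720 genes (highest other split 0), S228E against WT 1 (highest other 0) and S228E against S228A 690 (highest other 0), and in each comparison 1 split, the real one, gave as many.

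The S228A libraries carried high pheromone response transcripts and low histone, G1/S and G2/M transcripts. RNA from cells of the opposite mating type as the source of the whole pattern is argued against by the 7 a-specific genes, which alpha cells do not make and whose lowest lower 95% bound was log2 1.17, and a swap of single libraries by the first principal component, on which 0 of the 6 WT and S228E libraries lay nearer to the S228A mean; an exchange of whole groups was not tested. A smaller part of alpha-cell RNA stays open: STE3 had an upper 95% bound of log2 0.39 but lay near 3 CPM and stood at 0.23 without WT replicate 3, and SAG1 (1.72) and MF(ALPHA)2 (0.98) were called higher. MF(ALPHA)1 was not called in the main fit, at 0.426 CPM in WT and 0.856 CPM in S228A. Also open is whether the substitution or a condition of the 3 S228A cultures, such as exposure to mating pheromone from a few alpha cells or from the medium, may be the source: 0 of the 3 S228A libraries lacked the pattern, so the condition and the allele cannot be told apart in this design, and a swap with strains outside the series was not tested. A pheromone-arrested culture is therefore a hypothesis and so is an effect of the alanine substitution on mating genes, and an S228A strain made again and grown beside WT would separate them.

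Few genes were called between S228E and WT, 3 in all. In simulated S228E libraries 94.0% of genes changed 2-fold were called by both thresholds, against 47.8% of genes changed 1.5-fold. As 200 genes changed there, this argues against too little power only for 2-fold changes within a response of that breadth. The Benjamini-Hochberg adjustment is stricter where few genes change, and that case was not simulated. ASP3-4, at log2 1.68 in S228E, was not called (edgeR adjusted p = 0.189). A biological explanation, that glutamate at this position leaves the mid-log transcriptome close to that of WT, remains untested beyond these 3 libraries. Smaller changes, and larger changes of a few genes, stay open.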

How the results depend on the processing

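All alternatives here were planned before the data were examined; the test of scaling factors by the shift between gene lists was chosen only after the result was seen. The count for S228A against WT (747) stayed within 1.5 times under 10 other settings of scaling, filter, tool, block and samples, with 611 of 617 genes shared under the stricter filter and 710 of 724 under DESeq2; it was 2144 with no fold threshold, 362 at a fold over 2 and 382 with glmTreat, which the thresholds themselves bring about. For S228E against S228A (680) these were 1822, 344 and 373. The count for S228E against WT (3) was 5 with DESeq2, 1 at a fold over 2, 0 with glmTreat, 1 with only the 6 libraries and 1 with the replicate block; the cause was not tested. Leaving out 1 library gave 705 to 768, 643 to 693 and 1 to 2 genes for the 3 comparisons in the order given. No scaling moved the split of higher and lower calls by 10 percentage points or the median of all genes by 0.1.

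The replicate numbers did not pair the libraries: correlations of same-numbered deviations ran from -0.251 to 0.229, and 2 of 9 libraries lay closest to one of their own number. The replicate block gave 738 genes for S228A against WT, 1 for S228E against WT and 666 for S228E against S228A.

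The number of lists called for S228A against WT, S228E against WT and S228E against S228A (16, 9 and 17) was 0, 0 and 2 with an estimated correlation. Fry called 19, 0 and 20. Leaving out 1 library gave 16 to 18, 5 to 17 and 11 to 20 lists. In S228E against WT the direction of 3 lists turned when 1 library was left out, at a camera adjusted p from 7.61e-22 to 0.533 for cytosolic ribosomal proteins, 2.62e-05 to 0.656 (0.567 when turned) for general stress and 5.99e-05 to 0.773 for glucose-repressed carbon use. With windows of 20 and 50 kb the subtelomeric list had adjusted p of 0.388 and 0.333 in S228A and 0.00109 and 0.0689 in S228E against WT, and 0.0224 and 0.0793 between the mutants. The correlation of fold changes was 0.132 to 0.243 when 1 library was left out.

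The SET1 fold change in S228A was -0.00730 with upper-quartile scaling and -0.0200 to 0.105 when 1 library was left out. Uncalled genes near 0 also turned sign, with ranges of log2 fold change over the left-out libraries of -0.0909 to 0.0171 (BRE2, S228A), -0.132 to 0.0115 (SWD1, S228A), -0.0282 to 0.0616 (SWD1, S228E; -0.00363 with upper-quartile scaling), -0.00654 to 0.109 (SDC1, S228E), -0.105 to 0.00266 (SWD2, S228E against S228A), -0.238 to 0.234 (STE3, S228A) and -0.125 to 0.630 (MF(ALPHA)1, S228E). Of 112 named genes called in S228A against WT 102 kept the call in every setting of scaling, filter, tool, block and samples and none turned sign, while 78 were called at a fold over 2 and 87 with glmTreat. Most of these genes were picked for a large fold or a small p in the same fit, so the shares do not describe all called genes. A wrong scaling factor per library moves all genes alike. As the source of the whole pattern in S228A it is argued against by the shift of log2 5.43 between the 20 pheromone response genes and 52 histone, G1/S and G2/M genes (95% rank-based interval over genes, which are not independent, 4.54 to 6.49). Depth limits rows of a few counts, such as YLR161W with 18 counts in the WT group.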

Other observations

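The tests below on Ty3 repeats that leave out tR(UCU)G3 and tH(GUG)E2 or transposons were chosen only after the result was seen; the other tests on Ty3 repeats and sequence motifs were chosen after the called genes had been seen and before they were run. Several groups not described in the report also held called genes in S228A, although camera did not place the lists apart. Over all 6133 tested rows 268 were called higher and 479 lower. Called members near that share, as in the ergosterol list, or below it, as in the autophagy list, do not set a list apart. Of 16 daughter-cell and M/G1 genes 6 rose and 2 fell (camera adjusted p = 0.146), with AMN1 at log2 1.55 ± 0.10, SCW11 at 1.26 ± 0.09 and the chitinase gene CTS1 at 0.94 ± 0.09. Of 26 iron regulon genes 5 fell and 1 rose (camera adjusted p = 0.311), with FIT3 at -3.18 ± 0.28, FIT2 at -3.01 ± 0.28 and ARN2 at -1.48 ± 0.18. Of 20 cell wall integrity genes 4 rose and 2 fell (camera adjusted p = 0.242), with the chitin synthase gene CHS1 at 1.56 ± 0.09 and GAS1 at -1.19 ± 0.09. Of 17 hexose transporter genes 3 rose and 2 fell (camera adjusted p = 0.398): HXT11 was at 2.29 ± 0.14 and HXT9 at 2.71 ± 0.18, near-identical genes whose reads cannot be split with certainty, and HXT1 at -1.05 ± 0.12 and HXT3 at -0.60 ± 0.08, a call lost in 4 of 16 alternative settings.

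In the ergosterol list 2 of 27 genes rose and 2 fell (camera adjusted p = 0.337), with ERG4 at log2 -1.11 ± 0.10, ERG3 at -1.12 ± 0.11, MVD1 at 0.68 ± 0.07 and ERG24 at 0.77 ± 0.09. Of 26 early meiotic genes 4 rose and 1 fell (camera adjusted p = 0.617), with NDJ1 at 1.4 ± 0.11, MSH5 at 0.94 ± 0.09 and SPO16 at -1.98 ± 0.24. Of 35 autophagy genes 1 rose, ATG1 at 0.63 ± 0.09 (not called without WT replicate 2), and none fell (camera adjusted p = 0.831). PGU1, a pectinase gene near a chromosome end, rose from 15.1 ± 2.22 to 126.9 ± 11.4 CPM in S228A (log2 3.07 ± 0.11; edgeR adjusted p = 6.07e-10).

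A candidate explanation for the genes that rose in S228A is transcription through binding sites of Ste12, the factor of the pheromone response. Its motif TGAAACA stood in the 500 bp upstream of 77 of 198 called-higher coding genes (38.9%) and of 592 of 5520 other tested coding genes (10.7%), an odds ratio of 5.29 (95% interval 3.88 to 7.20; Fisher's exact test, 2-sided, p = 8.32e-24). Upstream of called-lower genes the odds ratio was 0.853 (0.610 to 1.17). The MluI cell cycle box ACGCGT, which G1/S genes carry, stood upstream of 74 of 458 called-lower genes (16.2%) and of 4.62% of the others, an odds ratio of 3.98 (2.96 to 5.29; Fisher's exact test, 2-sided, p = 2.59e-18), against 1.10 (0.554 to 2.0) for called-higher genes. Both enrichments go with the hypothesis of a pheromone-type G1 arrest, and neither says what set it off. The 20 pheromone response genes and the 22 lower G1/S genes, which had prompted that hypothesis, were not left out of these tests. The enrichments therefore partly restate the list results and are not independent of them.

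The tRNA rows that rose in S228A may carry transcripts that start in a Ty3 long terminal repeat next to the tRNA gene. Of the 12 rows called higher 8 (66.7%) lay within 500 bp of an annotated Ty3 repeat, against 1 of 8 other tested tRNA rows (odds ratio 12.1, 95% interval 1.00 to 704; Fisher's exact test, 2-sided, p = 0.0281), and all 8 lay within 50 bp. Rows such as tI(AAU)I2, at 0 CPM in WT and S228E and 4.53 CPM in S228A, passed the count filter only through the S228A libraries. Rows with or without a repeat that stayed low in every strain were not tested, so these shares cannot decide the question. The surroundings of tR(UCU)G3 and tH(GUG)E2 had prompted the idea, and without these 2 rows it was 6 of 10 (60.0%) against 1 of 8 (odds ratio 9.11, 95% interval 0.708 to 548; Fisher's exact test, 2-sided, p = 0.0656), so the explanation stays open. Among tested rows other than tRNA and transposons, 4 of 213 called higher lay within 500 bp of such a repeat, against 22 of 5845 others (odds ratio 5.06, 95% interval 1.26 to 15.1; Fisher's exact test, 2-sided, p = 0.0121), or 13 of 256 against 22 of 5857 with transposons, which can adjoin their own repeats. A general rise of reads from tRNA genes stays open too, since 4 of the 11 tested tRNA rows without a nearby Ty3 repeat (36.4%, exact binomial 95% interval 10.9% to 69.2%) were also called higher, too few rows to decide.

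Of auxotrophic marker genes, LEU2 had 0 counts in all 9 libraries, URA3 had 2 counts in the WT group and 0 in the others, and MET17 had 1 count in S228A and 0 elsewhere. HIS3 was at 203.1 ± 21.5 CPM and LYS2 at 171.9 ± 10.6 CPM in WT, with like values in the mutants (199.8 ± 9.25 and 173.5 ± 8.57 CPM in S228A, 188.9 ± 4.77 and 180.0 ± 14.5 CPM in S228E).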
